A study of Mus musculus with 2 samples.

How the data were processed

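Ribosome profiling sequences the short mRNA stretches that ribosomes shield from nuclease, so a gene's count reflects both how much of its mRNA the cells held and how many ribosomes sat on it. The series holds 2 such libraries from mouse lung fibroblasts, 1 labelled IR and 1 labelled NC, and the groups were taken from the sample titles. The labels do not spell out either abbreviation, give no dose or time, and name no replicate. Per the labels' protocols, cells were treated with cycloheximide, lysed and digested with nuclease, footprints were recovered by size exclusion and gel selection, rRNA was removed, and the cDNA was circularised, amplified and sequenced on an Illumina NovaSeq. No molecular identifiers are mentioned there, so PCR copies of 1 footprint may be counted more than once.

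The deposited table lists 14886 protein-coding genes with whole-number counts of mapped reads, per the file headers. The submitters' processing notes name cutadapt 1.9.3, Bowtie, TopHat2, HTSeq 0.9.1, edgeR, DESeq2 and the build mm10, without a role or order. The annotation release, the strand setting, the footprint lengths kept and the handling of reads with several matches are not given in the sources used here. Genes with near-identical copies (ribosomal proteins, histones) and overlapping or antisense genes are therefore less certain. Beside the counts, the authors deposited log2 CPM values from edgeR, per the file headers. For the IR library these, put back on the CPM scale, were a straight line of the counts with a prior count of 2.01, and the library size they imply, 791008, equals the one obtained here by TMM scaling. The other column of log2 CPM, 1 in number, was not used.

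Symbols and coordinates are those of the table. Of its 14886 rows, 13877 carry a symbol of the GRCm38.p6 RefSeq gene table, 828 matched it through an older symbol and 181 did not match. Gene starts lay within 5000 bp of that table's for 94.6% of the matched symbols. Of rows that shared a symbol (18 rows, 9 symbols), the one with the higher count entered a gene list.

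Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, 0.890 for IR and 1.12 for NC. The log2 ratio of IR over NC was taken after adding a pseudocount of 1 to the scaled counts, for genes with a mean of at least 20 counts over both libraries. Folds and their intervals carry no pseudocount. With 1 library per group there is no replicate spread and no test between the conditions, so no p-value is given. Each fold has a 95% interval from the exact (Clopper-Pearson) binomial interval of the IR share of the gene's counts. These intervals, and the limit of 3 counts behind a count of 0, cover counting error only, taking each read as a separate footprint. That limit corresponds to 3.79 CPM in IR and 3.84 CPM in NC.

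Gene lists fitting lung fibroblasts, irradiation, fibroblast-to-myofibroblast transition, glycolysis, tRNA modification and translation, and markers of other lung cell types, were fixed before the data were examined, 35 in all. A list is described by the median log2 ratio of its members above the floor minus the median of all genes above it, with a binomial order-statistic 95% interval of the median. Its percentile is that of its median among 10000 random lists of the same size matched on mean count in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5. This describes these 2 libraries and is no test of the conditions. The 6 lists with fewer than 5 members above the floor have values only. The genes named were also set by rule: the 10 highest and 10 lowest ratios among genes with at least 100 counts in the higher library and none at 0, the 2 highest and 2 lowest members of each list described, 8 genes of the study's question, and the 5 genes with the highest mean count. Genes outside this rule are marked as chosen after their values were seen.

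The procedure was tested on simulated counts for this comparison (6171 genes above the floor, 200 of them changed). The median log2 ratio was 0.93 for genes raised 2-fold and 1.99 for genes raised 4-fold, and 93.0% of the intervals held the true fold. The 200 changed genes were drawn with counting error alone, without the extra spread given to the other genes. This coverage therefore concerns counting error only, not other differences between 2 libraries. Of 200 unchanged lists of 20 genes, 3.5% stood apart, against 51.0% of lists shifted by 0.5 on the log2 scale. The simulated genes varied independently, and as many were raised as lowered. These rates therefore do not cover list members that share a bias, or libraries that differ in composition. Other scalings, floors, pseudocounts, list summaries and matchings were tried. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Matched mRNA libraries were not analysed here, so translational efficiency was not computed, and coding sequences were not used.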

Results

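Ribosome footprints were counted in mouse lung fibroblasts in 1 library labelled IR and 1 library labelled NC. The title of the series concerns radiation-induced lung fibrosis, rosmarinic acid and the transition of fibroblasts to myofibroblasts, the contractile, matrix-producing cells of fibrotic tissue. Its design text gives ribosome profiling the purpose of finding target mRNAs. Whether the IR fibroblasts were themselves irradiated is not stated in the labels. The IR library held 888835 counts and the NC library 695446, over 14886 protein-coding genes, of which 13306 and 13009 had at least 1 count. The median gene had 12 counts in each library, so most genes were measured with little precision. A mean of at least 20 counts was reached by 5989 genes, and 1332 genes reached 100. There are no replicates, so every difference below is one between these 2 libraries, with an interval for counting error only.

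The comparison of IR with NC addresses which genes gave more or fewer ribosome footprints in the IR library, through mRNA amount, ribosomes per mRNA or both. Across the 5989 genes, log2 scaled counts of the libraries correlated with Pearson's r = 0.74 and Spearman's rho = 0.69. These are correlations across genes, which are not independent replicates. In the IR library 679 genes (11.3%) were at least 2-fold higher and 685 genes (11.4%) at least 2-fold lower. This balance depends on scaling and depth: total-count scaling gave 412 and 1199, and a floor of 100 counts gave 164 and 59. Splitting each gene's counts at random between the libraries gave on average 13.7 and 14.5 such genes over 100 draws. The log2 ratio had an SD of 0.98 over genes, against 0.30 from counting alone. For 270 genes the interval lay wholly above 2-fold higher and for 175 genes wholly beyond 2-fold lower. If each read stands for a separate footprint, counting error accounts for few of these differences. PCR copies of footprints would make that error larger, by an amount not known here. How far 2 libraries of one condition would differ is also not known from these data.

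Of the genes in the study's question, those of the matrix and cytoskeleton were abundant and slightly higher in IR. Fn1, which encodes fibronectin, had 3526 counts in IR and 2433 in NC, a fold of 1.43 (95% interval 1.36 to 1.51). Acta2, which encodes smooth muscle actin and is the usual myofibroblast marker, lies on chromosome 19 at 34241090 to 34255336 (mm10). It had 820 and 562 counts, a fold of 1.44 (1.29 to 1.61). Col1a1, the main chain of type I collagen, differed little, with 3455 and 3124 counts and a fold of 1.09 (1.04 to 1.15). Vim, the intermediate filament vimentin, had a fold of 1.16 (1.03 to 1.30). Fn1, Acta2, Col1a1 and Vim all lie in the top 20th of genes by mean count, where the median log2 ratio was 0.36 (0.26 to 0.47). Against that median, Col1a1 (log2 ratio 0.13) and Vim (0.21) lay lower, and Fn1 (0.52) and Acta2 (0.53) higher. Scaling by total counts lowers every log2 ratio by about 0.34 and puts Col1a1 and Vim below 1-fold. Cdkn1a, the p53-induced cell cycle inhibitor p21, had 65 and 38 counts and a fold of 1.69 (1.12 to 2.59).

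Pfkfb3, the glycolytic regulator whose acetylation the series' design names, lies on chromosome 2 at 11471430 to 11502101. It had 0 counts in IR and 9 in NC. The exact 95% interval of its fold ran from 0 to 0.501. The NC count itself has an exact Poisson interval of 4.12 to 17.1, so this rests on few reads. The subunits of the tRNA m7G methyltransferase were too shallow to separate. Mettl1 had 20 and 14 counts, a fold of 1.41 (0.678 to 3.02), and Wdr4 had 7 and 12 counts, a fold of 0.576 (0.192 to 1.59).

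Of the 29 gene lists with enough members, 7 stood apart as higher in IR and 3 as lower, where 1.45 in all would be expected by chance for independent lists.

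**Figure D1:**
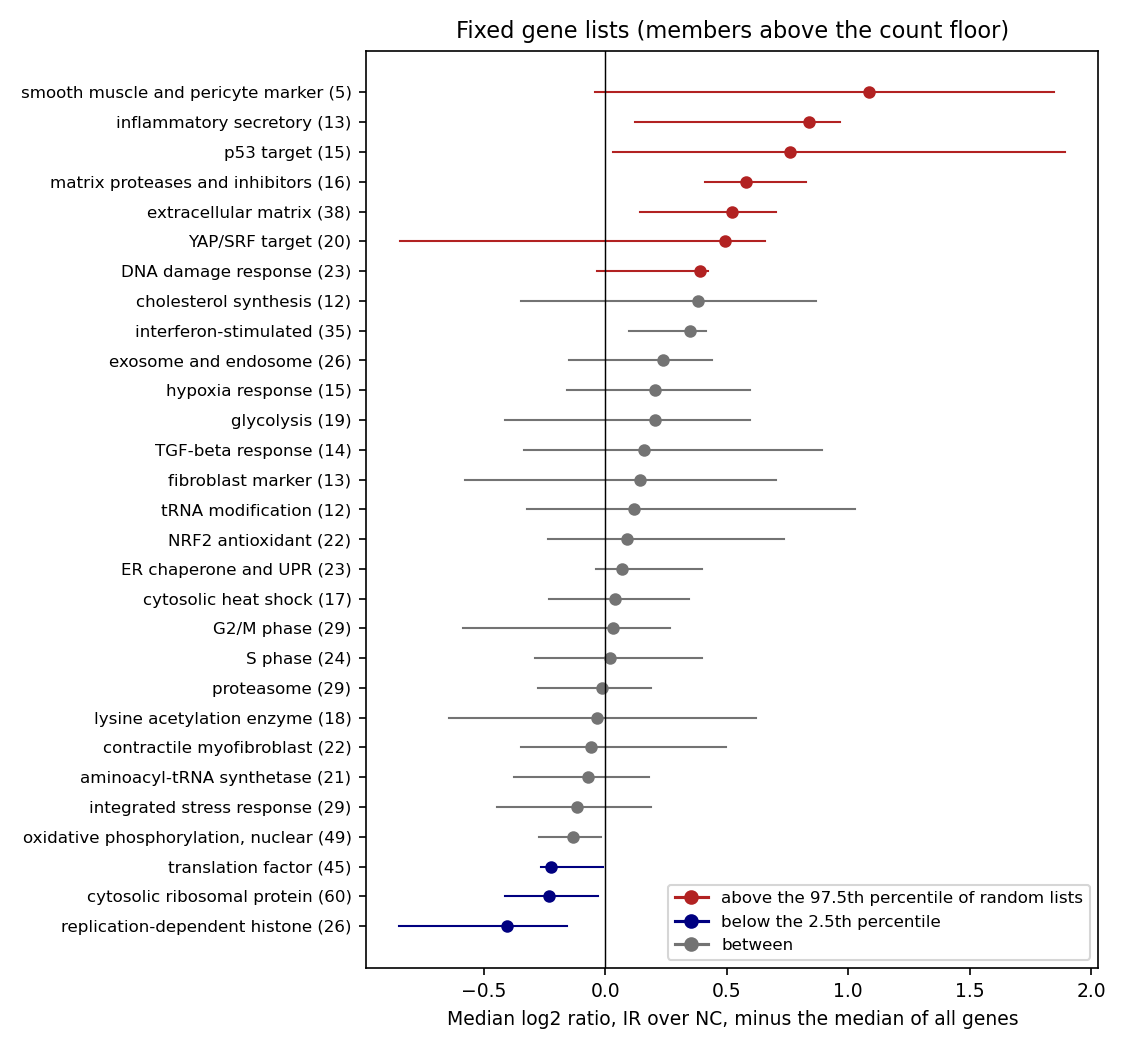
Each row is a gene list fixed beforehand, with the number of members above the floor of 20 mean counts; the horizontal axis is the median log2 ratio of IR over NC minus the median of all genes, and bars are 95% intervals of the median over members (the full range for the list of 5). The 7 lists in red stand above and the 3 in blue below nearly all random lists matched on count.

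The extracellular matrix list stood apart as higher in IR, as did the list of smooth muscle and pericyte markers (percentile 99.6), while fibroblast markers did not (percentile 48.7). Mesothelial markers summed to 523 counts in IR and 129 in NC. Of the 38 extracellular matrix genes above the floor, 23 were higher and 4 lower beyond counting error, and 11 were neither. Their median lay 0.52 above that of all genes on the log2 scale (95% interval 0.14 to 0.70, percentile 99.5). Count-matched random lists themselves had a median of 0.15, so the excess over genes of like count was 0.37. Lum, the collagen-binding proteoglycan lumican, had 1349 counts in IR and 222 in NC, a fold of 6.0 (5.21 to 6.95). Col11a1, a fibrillar collagen chain, had 37 and 9 counts. At the other end Col3a1, the main chain of type III collagen, was 1.51-fold lower (1.32 to 1.73), with 348 and 519 counts, and Fbn2, a microfibril component, had 14 and 35. Of 16 matrix proteases and their inhibitors, 11 were higher beyond counting error and 0 lower, with a median of 0.58 (0.41 to 0.82, percentile 98.8). Adamts2, which trims procollagen, was 2.78-fold higher (1.54 to 5.27) and Plat, tissue plasminogen activator, 1.97-fold higher (1.62 to 2.40). Mmp2, a gelatinase, had 98 and 93 counts. The matrix list fell to percentile 93.7 and the protease list to 90.4 when only genes with a mean of 100 counts were kept.

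The inflammatory secretory list stood apart as higher in IR, and macrophage and leukocyte markers summed to 499 counts in IR and 350 in NC, a fold of 1.41 (1.23 to 1.62). Of the 13 secretory genes, 8 were higher and 1 lower beyond counting error, and the median was 0.84 (0.12 to 0.97, percentile 99.5). Ccl5, a chemokine for T cells and monocytes, had 66 and 7 counts, a fold of 9.31 (4.28 to 24.1). Ptgs2, the inducible cyclooxygenase, had 289 and 114, a fold of 2.5 (2.01 to 3.14). Vegfa was 1.29-fold lower (1.06 to 1.57), with 183 and 233 counts. Without Ccl5 the list's percentile was 95.3, and with all genes above 0 in both libraries it was 89.7, so at these settings it did not stand apart. With a floor of 100 counts, which also leaves Ccl5 out, the 7 remaining members did, with a median of 0.77 (percentile 98.5). Interferon-stimulated genes were abundant in both libraries and did not stand apart, with a median of 0.35 (0.10 to 0.41) at percentile 96.9. Among these 35 genes 15 were higher and 4 lower beyond counting error. Cxcl10 had 629 and 122 counts, a fold of 5.09 (4.19 to 6.24), and Oasl1 161 and 38. Parp14 had 13 and 51 counts, and Ifi27 148 and 312.

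Targets of the p53 tumour suppressor were higher in IR as a group, with members in both directions. Of 15 above the floor, 9 were higher and 2 lower beyond counting error, with a median of 0.76 (0.03 to 1.89, percentile 99.9). With a floor of 100 counts, too few p53 targets were left to score the list. Phlda3, an inhibitor of Akt signalling, had 80 and 14 counts, a fold of 5.65 (3.18 to 10.8). Gtse1, a regulator of p53 in G2, had 175 and 31, a fold of 5.58 (3.79 to 8.46). Bax, which triggers apoptosis at mitochondria, was 1.92-fold lower (1.27 to 2.93), and Ei24 had 15 and 28 counts. The DNA damage response list stood apart by its median of 0.39 (percentile 98.6), whose interval of -0.03 to 0.42 holds 0. In it 4 of 23 members were higher and 3 lower beyond counting error, and its mean did not stand apart (percentile 85.9). With a floor of 100 counts the median was 0.033 (percentile 65.2). Gadd45b, a stress-induced growth arrest gene, was 2.41-fold higher (1.80 to 3.26), while its relative Gadd45a was 1.96-fold lower (1.52 to 2.54). H2afx, the histone variant phosphorylated at DNA breaks, had 83 and 47 counts, and the checkpoint kinase gene Chek1 had 16 and 31.

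**Figure D2:**
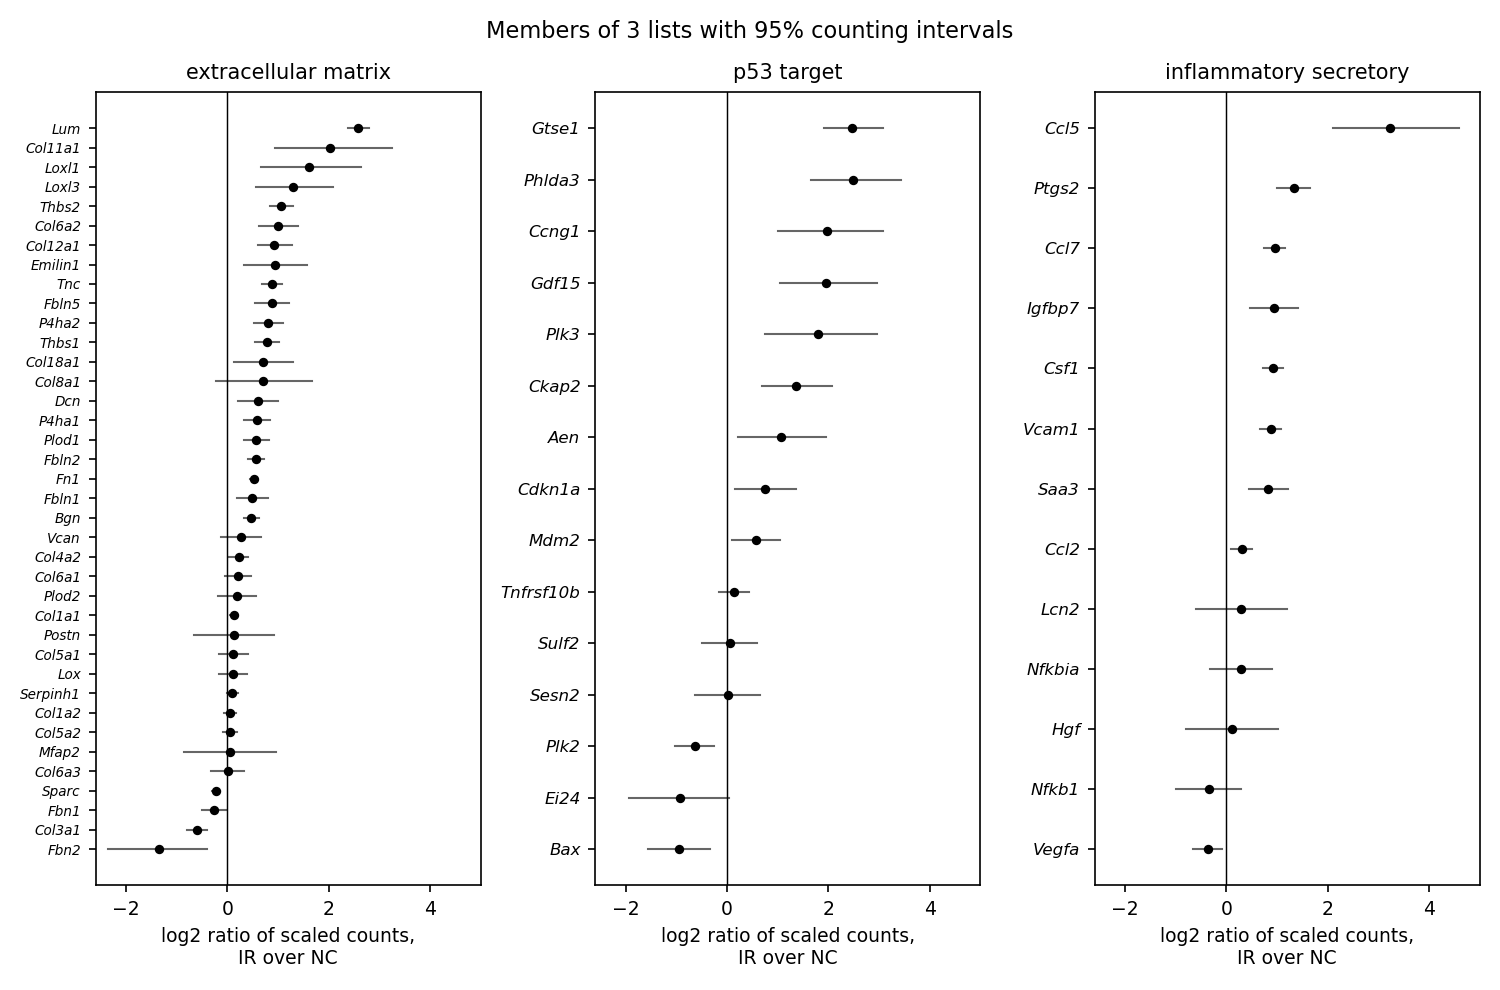
Points are the log2 ratio of scaled counts (IR over NC, no pseudocount) of each member above the floor in 3 lists, and bars are 95% counting intervals. Most matrix, p53-target and inflammatory genes lie right of 0, from Ccl5 at 9.31-fold to members such as Col3a1 and Bax on the left.

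Lists of translation factors, cytosolic ribosomal proteins and histones stood apart as lower in IR, each with members in both directions, and aminoacyl-tRNA synthetases did not stand apart. Of 45 translation factor genes, 16 were lower and 6 higher beyond counting error, with a median of -0.22 (-0.26 to -0.01, percentile 0.56). That list did not stand apart by its mean (percentile 2.93) or among unmatched random lists (percentile 5.10). Eif5b, which joins the ribosomal subunits, was 2.72-fold lower (2.14 to 3.49), and Eif2b5, a subunit of the eIF2 exchange factor, 2.02-fold lower (1.19 to 3.55). Eif2b4, another subunit of that factor, had 38 and 17 counts, and Eif3j1 56 and 31. Of 60 cytosolic ribosomal protein genes, 22 were lower and 11 higher, with a median of -0.23 (-0.41 to -0.03, percentile 0.89). Rpl11 had 15 and 65 counts and Rpl21 12 and 45, whereas Rpl19 had 38 and 9 and Rpl39 42 and 11. Ribosomal proteins too did not stand apart by the mean (percentile 3.23) or among unmatched lists (percentile 2.79), and summed counts gave the opposite sign, 0.07 on the log2 scale. Reads of ribosomal protein genes can be split among their many pseudogenes, and the handling of such reads is not known here. Replication-dependent histones, made in S phase, had a median of -0.40 (-0.85 to -0.16, percentile 1.79), with 10 of 26 lower and 2 higher. Without the member farthest from the median they did not stand apart (percentile 2.93). Hist1h3f was 3.16-fold lower (2.21 to 4.61) and Hist1h1c 2.96-fold lower (1.91 to 4.73), while Hist1h4h and Hist1h2be were higher, at 2.21-fold (1.30 to 3.89) and 1.63-fold (1.18 to 2.27).

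Contractile and TGF-beta response genes, the other parts of the myofibroblast programme, did not stand apart. Of 22 contractile genes, 6 were higher and 7 lower beyond counting error, with a median of -0.06 (-0.35 to 0.49, percentile 10.4) and a mean of 0.04. Against the median of count-matched random lists, the contractile median lay at -0.23. Palld, the actin-bundling palladin, had 752 and 213 counts, a fold of 3.49 (2.99 to 4.08), and Des, desmin, 35 and 9. Tpm1, a tropomyosin, was 2.23-fold lower (1.91 to 2.62) and Myh10, a non-muscle myosin, 2.07-fold lower (1.70 to 2.54). The 14 TGF-beta response genes had a median of 0.16 (-0.33 to 0.89, percentile 66.8), with 4 higher and 2 lower. Ctgf, a matricellular growth factor now named Ccn2, was 3.16-fold higher (2.70 to 3.70), and Ltbp2 2.24-fold higher (1.48 to 3.46). The repressors Tgif1 and Skil had 34 and 70, and 37 and 59 counts. The YAP and SRF target list split, with 11 of 20 members higher and 8 lower. Its median of 0.49 (-0.84 to 0.66) stood at percentile 98.1, its mean of 0.08 at 43.8, and its median with a floor of 100 counts at 86.6. In it Ctgf and Nuak2 were higher, and Amotl2 and Ankrd1 were 2.5-fold (1.97 to 3.20) and 2.30-fold lower (1.62 to 3.32).

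Glycolysis, which the study assayed, did not stand apart. Of 19 genes, 8 were higher and 4 lower beyond counting error, with a median of 0.20 (-0.41 to 0.60, percentile 77.3). Pfkl, the liver-type phosphofructokinase, had 600 and 293 counts, a fold of 2.02 (1.76 to 2.33), and Eno3 79 and 40. Pgam1 was 1.54-fold lower (1.25 to 1.91), and Pfkp, the platelet-type phosphofructokinase, 1.48-fold lower (1.12 to 1.97). Nuclear oxidative phosphorylation genes had a median of -0.13 (-0.27 to -0.02, percentile 11.2), with 8 of 49 higher and 11 lower. Of the mitochondrial genes listed, mt-Co3 had 479 and 489 counts and mt-Nd4 331 and 186. Among 12 tRNA modification genes the median was 0.12 (-0.32 to 1.03, percentile 70.6). Its direction is not settled: without a floor, the 39 genes above 0 in both libraries had a median of -0.18 (percentile 19.4). Thg1l, which adds a guanosine to tRNA-His, was 2.25-fold higher (1.82 to 2.79), and Qtrt1, a subunit of the queuosine-inserting enzyme, 2.67-fold higher (1.5 to 4.97). Enzymes of lysine acetylation went both ways, with 4 of 18 higher, 5 lower and a median of -0.03 (-0.64 to 0.62, percentile 42.8) against a mean of 0.13. The mitochondrial deacetylase gene Sirt3 had 98 and 5 counts, a fold of 19.4 (8.02 to 61.0), and it overlaps Ric8a. The acetyltransferase gene Crebbp was 3.45-fold lower (2.23 to 5.51).

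Cell cycle, stress, proteostasis and other metabolic lists did not stand apart from random lists. The S phase median was 0.02 (percentile 48.1) and the G2/M median 0.03 (percentile 56.5), with a mean of -0.12. Integrated stress response genes had a median of -0.12 (percentile 6.86), aminoacyl-tRNA synthetases -0.07 (percentile 12.6), ER chaperones 0.07 (percentile 28.0), cytosolic heat shock genes 0.04 (percentile 47.6) and proteasome genes -0.01 (percentile 37.6). NRF2 antioxidant genes stood at 0.09 (percentile 67.3), hypoxia genes at 0.20 (percentile 74.4), cholesterol synthesis at 0.38 (percentile 94.0) and exosome and endosome genes at 0.24 (percentile 85.5). For S phase the interval ran from -0.29 to 0.40 and for ER chaperones from -0.04 to 0.40, so smaller shifts could have been missed.

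Markers of other cell types were mostly sparse. The 13 fibroblast markers above the floor had a median of 0.14 (percentile 48.7). Epithelial markers had 121 counts in IR and 43 in NC over 16 genes, of which Abca3 held 73 and 27. Macrophage and leukocyte markers had 499 and 350 counts, mostly in Cd74 (244 and 169) and Cd3e (178 and 157). Mesothelial markers had 523 and 129 counts, mostly in Wt1, at 417 and 77. Of the smooth muscle and pericyte markers 5 were above the floor, 4 of them higher in IR beyond counting error, with a median of 1.09 (range -0.04 to 1.85, percentile 99.6). Synpo2 had 136 and 39 counts and Abcc9 129 and 133. Endothelial markers had 7095 and 2773 counts, of which Emcn, endomucin, held 6842 and 2618. Blood and serum genes had 4 and 6 counts.

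Single genes were ranked among those with at least 100 counts in the higher library and none at 0. Under that limit, the highest in IR over NC were the predicted gene Gm6665 (313 and 2 counts, 155-fold, 42.4 to 1282), which overlaps Wdr33, the zinc finger gene Zfp81 (1831 and 25, 72.4-fold, 48.9 to 112), Sez6l (182 and 4) and Camsap3 (299 and 8). After these in that ranking came Lipf, Gpr81, Oprd1, Tmcc2, Nbeal2 and Cnksr2, from 17.1-fold down to 9.55-fold. The lowest under the same limit was Gsg1l, with 3 counts in IR and 1297 in NC, 438-fold lower (149 to 2125). Dnd1, a germ cell RNA-binding protein gene on chromosome 18 at 36763671 to 36766214 that overlaps Wdr55, had 101 and 9152 counts, 91.7-fold lower (75.4 to 113). Tlx2 had 1 and 194 counts, Prph2 1 and 111, Cmya5 4 and 160, Wdr66 6 and 213 and Muc5ac 5 and 155. The remaining 3 of the 10 lowest were 4931406B18Rik, Stra6 and Pkd1l2, from 21.6-fold to 18.1-fold lower. Of these 20 genes, 4 overlap another protein-coding gene, whose reads cannot be told apart without the strand setting. The same limit holds for other genes named above: Eif5b overlaps Rev1, Eif2b4 Snx17, Eif3j1 Spg11, Cxcl10 Art3 and Ifi27 Ifi27l2a. Likewise, Pfkp overlaps Pitrm1, Mettl1 Eef1akmt3 and Abca3 Abca17.

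A few genes held much of each library, and gene counts alone do not show whether their reads are ribosome footprints. Actr10, a dynactin subunit gene on chromosome 12 at 70937857 to 70964718, had 55311 counts in IR, 6.22% of the library (exact 95% interval 6.17% to 6.27%), and 15961 in NC, 2.30% (2.26% to 2.33%). Cacna2d2, a calcium channel subunit gene, had 24182 and 10219, and Ptges3, the co-chaperone p23, 23125 and 9145. Snrpb, a core spliceosome protein gene, was 1.2-fold lower in IR (1.17 to 1.23), with 11405 and 13481, and Chst8 had 10127 and 11024. The 10 most abundant genes of each library, ranked separately, took 20.3% of counts in IR and 12.1% in NC. In the top 20th of genes by mean count, the median log2 ratio was 0.36 (0.26 to 0.47), against -0.02 over all genes.

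**Figure D3:**
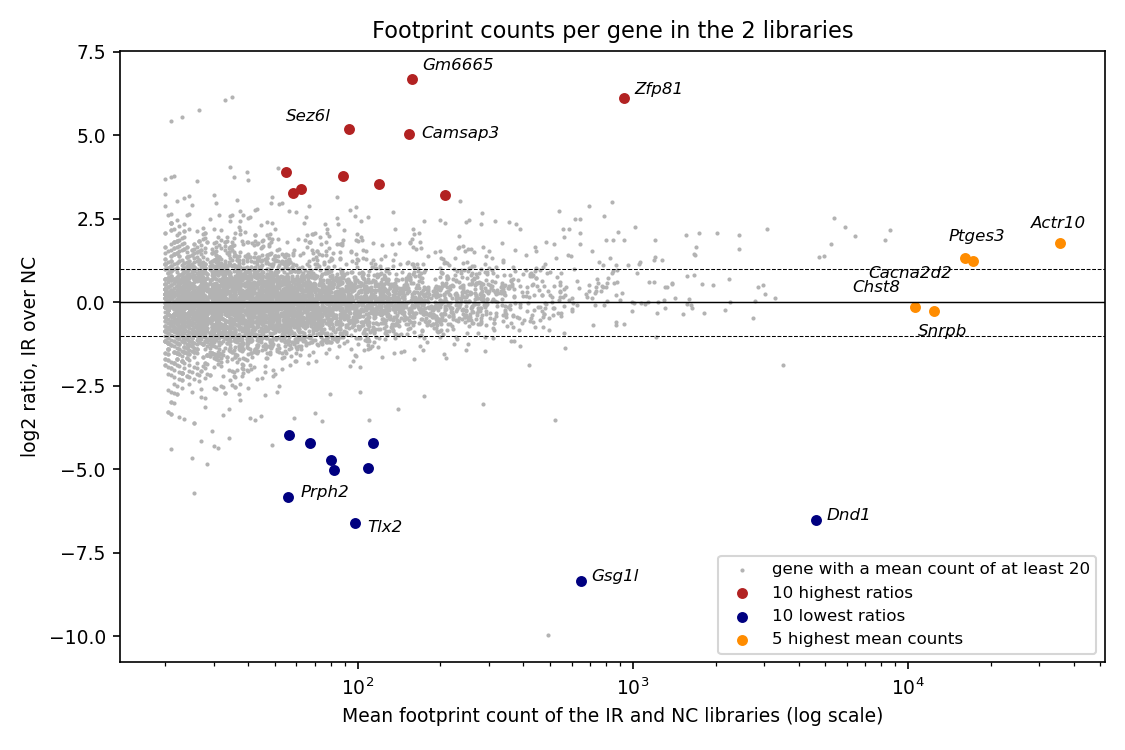
Each point is a gene with a mean count of at least 20; the horizontal axis is the mean count of both libraries on a log scale, the vertical axis the log2 ratio of IR over NC with a pseudocount of 1, and dashed lines mark 2-fold. The 3 genes with the highest mean counts, Actr10, Cacna2d2 and Ptges3, lie above the upper dashed line.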

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

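No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. All alternatives were planned except matching on gene span and leaving out the 100 highest-count genes, which were chosen after seeing the data. Counts of genes at least 2-fold higher and lower (679 and 685) were 705 and 673 with median-of-ratios and with upper-quartile scaling, whereas total-count scaling, which moves the median of all genes to -0.34, gave 412 and 1199 (25.6% higher, against 49.8%) and turned Col1a1 to -0.21 and Vim to -0.12 on the log2 scale. Without a floor, where only the 11429 genes above 0 in both libraries were kept, the counts were 1775 and 1895. They were 164 and 59 with a floor of 100 counts (73.5% higher), 1315 and 1374 at 1.5-fold, 146 and 123 at 4-fold, and 270 and 175 for intervals beyond 2-fold. The correlation across genes was 0.83 without a floor, over those same 11429 genes, and 0.69 with a floor of 100.

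Of the 10 lists that stood apart, 10 did so with either pseudocount, with 10 matching bins, with matching on span and without the 100 highest-count genes, though 6 of them hold none of those genes. With a floor of 100 counts, 3 of the 8 that could be scored did. The p53-target list and the smooth muscle and pericyte list kept too few members at that floor to be scored. There the medians were 0.37 for matrix, 0.49 for proteases, 0.42 for YAP and SRF targets, 0.033 for DNA damage and -0.17 for ribosomal proteins, none apart. Those of inflammatory genes (0.77), histones (-0.88) and translation factors (-0.35) stood apart. Fewer members were left. With means in place of medians, DNA damage (0.19), YAP and SRF (0.077), ribosomal proteins (-0.19) and translation factors (-0.17) no longer stood apart. Unmatched random lists ended the standing of ribosomal proteins (-0.23) and translation factors (-0.22). Without the farthest member, inflammatory genes (0.58) and histones (-0.38) did not stand apart, nor did inflammatory genes (0.37) without a floor. Smooth muscle and pericyte markers had too few members to be scored without the farthest one. The summed counts of ribosomal proteins reversed to 0.069. The causes of these changes were not tested. Interferon-stimulated genes came to stand apart among unmatched lists (0.35) and without the 100 highest-count genes (0.36). Among 785 alternative values of 157 named genes, 751 stayed within the counting interval, 32 moved outside it, and 2, both of genes whose interval excludes 1, changed sign. With total-count scaling Mmp2, Adamts1, Cd3e and Calb2, whose intervals include 1, also changed sign. Depth limits most single genes: with 3 counts as the limit, a gene with 0 counts in IR may still lie anywhere up to 3.79 CPM.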

Other observations

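The grouping of genes by the letters their symbols share, and the tests of small RNA genes, sensory receptor genes, gene span, ER chaperones and the 100 highest-count genes, were chosen after the result was seen. Of 59 groups by symbol with at least 10 members above the floor, 3 stood apart as higher and 6 as lower, where 2.95 would be expected by chance. Letters do not make a family, so a group can hold unrelated genes. The 89 genes named Slc, mostly solute carriers, had a median log2 ratio 0.32 above all genes (0.13 to 0.51, percentile 99.9), with 36 higher and 9 lower beyond counting error. The 64 genes named Tmem had 0.25 (0.01 to 0.38, percentile 98.6), and 11 genes named Arl 0.52 (-0.52 to 1.14, percentile 98.2). Lower in IR were 26 coiled-coil genes named Ccdc (-0.59, -0.92 to 0.39, percentile 0.11), though their summed counts were 4021 in IR and 2074 in NC, and 16 RNA-binding motif genes named Rbm (-0.42, -1.22 to -0.13, percentile 1.99), of which 8 were lower and 0 higher. Parp genes, 10 in number, had -0.79 (-1.89 to 0.39, percentile 0.73). The Eif and Hist groups overlap lists of the report. The 35 genes named Rpl had a median of -0.40 (-0.54 to -0.18, percentile 0.40) and the 31 named Rps, which include S6 kinases such as Rps6kb1, -0.03 (-0.28 to 0.24, percentile 32.3), a difference that was not itself tested. Among genes with 0 counts in 1 library and at least 60 in the other, chosen after their values were seen, Chl1 had 0 in IR and 982 in NC, and Cga 66 and 0.

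The 50 genes with the highest counts were higher in IR, with a median log2 ratio of 0.54, 20 of them at least 2-fold higher and 2 at least 2-fold lower. They took 32.3% of counts in IR and 21.5% in NC. Annotated small RNA genes inside them are argued against as a source: 1 of the 50 contained one (2.0%), against a median of 12.0% for genes of like span, percentile 0.89. Endothelial cells are argued against for the 6842 endomucin counts, since 16 other endothelial markers together had 253 in IR (upper Poisson limit 286), 3.70% of the endomucin counts. Reads that are not footprints may contribute: 202 listed receptor genes of smell, pheromone and taste, which fibroblasts are not known to use, had 1001 counts in IR and 497 in NC, and 571 and 420 without Olfr1217, a log2 ratio of 0.43 (0.24 to 0.61, counting error only). This depends on the scaling: total-count scaling, which moves the median of all genes to -0.34, would bring that interval to hold 0. The receptor counts are also few beside those of the 50 genes, 287005 in IR and 149751 in NC. They therefore do not show whether the reads of the 50 genes are footprints. A difference between the conditions stays open, with 1 library each.

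Matrix, protease, p53-target and inflammatory lists lay higher and ribosomal protein, translation factor and histone lists lower. Gene span, introns included, is argued against as the cause only at a coarse level. Among random lists matched on count and, in 4 bins, on span, 10 of 10 lists stood apart. Finer differences in span, and coding length, were not tested. Without the 100 highest-count genes, 4 of 4 lists that hold any of them still stood apart, and the other 6 lists hold none. The matrix list holds 8 of them among 38 members, so for it they are argued against as the cause. The protease list holds 2, and the YAP and SRF target and ribosomal protein lists 1 each. Leaving out so few members hardly moves a median, so for these lists the result decides nothing. Better recovery of ribosomes at the endoplasmic reticulum in the IR library could raise secreted and membrane proteins, as for the Slc and Tmem groups. ER chaperones, made there too, had a median of 0.068 (-0.04 to 0.40), an interval that holds 0 and overlaps that of the matrix list. Against the median of count-matched random lists, the chaperones lay at -0.11 (percentile 28.0) and the matrix list at 0.37 (percentile 99.5). The chaperones thus showed no rise beyond genes of like count, but their interval is wide. Better recovery at the endoplasmic reticulum therefore cannot be told apart from a response to the IR condition.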
